A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

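Messenger RNA levels were measured on 3 two-colour DNA microarrays of the budding yeast Saccharomyces cerevisiae. Per the labels, strain S288C was grown in rich glucose medium at 25 °C, and exponentially growing cultures received 2-aminobenzimidazole from a 500 mM stock to 5 mM for 2 h, while control cultures grew for the same time untreated. Polyadenylated RNA of the treated culture was labelled with Cy5 and that of the control with Cy3 on every array, so there were 0 arrays with the dyes exchanged. The series states that the hybridisations came from independent biological samples, and all 3 arrays formed a single group of treated over control. The title of the array numbered 1 carries an added letter H, which the labels do not explain.

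The deposited table holds, for each of 6272 spots and each array, a log ratio that is taken here as log2. Per the labels' description, spots with flag value 0 entered a LOWESS normalisation by the authors, which removes a trend of the ratio with brightness. Background correction, the scanner, the array type and the image software are not given in the sources used here. The log base and the direction of the ratio are not written in the table. A base of 10 would turn the highest value, 6.89, into a ratio of 7830000, which is beyond the range of a 16-bit scanner image, while base 2 gives 119 and a natural log 986. Base 2 was used as the customary choice and the natural log stays possible. The ratio was read as treated over control, which is likely because the labels put the treated RNA in the first channel and such tables by custom give test over reference. With the opposite direction, higher and lower exchange places throughout. Spots without a value are empty. Array 1 had 3321 values, array 2 had 5599 and array 3 had 5823, with medians of -0.051, 0.018 and -0.044 and SDs of 1.046, 0.872 and 0.981. No intensities were used here, so whether a spot was near background or saturated is unknown, and precision is limited by the number of arrays.

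Spots were named through the platform annotation of the series and its Entrez identifiers, which were looked up in the RefSeq gene table of assembly R64. Of the 6272 spots, 5308 had 1 gene symbol, 0 had several and 964 had none here. The identifiers of 5304 of these spots were in the RefSeq table. The named spots stood for 5203 genes, of which 88 had more than 1 spot. For 64 of these 88 genes all spots carried 1 identical value per array, and 24 had spots with different values. Spots of a gene were averaged per array. The test covered the 3039 genes with a value on all 3 arrays.

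Each gene's log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept only, eBayes, two-sided, Benjamini-Hochberg adjustment over the 3039 genes, threshold 0.05), with the values as deposited. The control RNA enters through the ratio, so each array carries its own control. The residual degrees of freedom were 2 per gene, and eBayes added a prior of 5.31. On simulated data for this comparison, over 3039 genes with the spread of the real ones, the test recovered 5.4% of genes changed 2-fold, 63.2% of those changed 4-fold and 78.2% of those changed 8-fold, and 3.2% of its calls were false. With no changed gene it made on average 0 calls. Genes were drawn independently in these simulations. Each draw changed 50 genes of each size, a smaller share of genes than was called in the real data. All simulated arrays had like noise, whereas the real arrays did not repeat each other equally. The rates may therefore differ for the real data.

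Before the data were examined, 46 gene lists were fixed from general knowledge of yeast. Members were matched by symbol, systematic name or a unique alias. Each of the 45 lists with 3 or more tested genes was set against all other genes with camera from limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 45 lists. In a simulation with independently drawn genes, a list of genes raised 2-fold was called and 0 of 50 unchanged lists were. It does not show how camera behaves for lists of correlated genes. The named genes followed a rule fixed at the same time. They were the 15 highest and the 15 lowest genes past the threshold with the same sign on all 3 arrays, up to 2 highest and 2 lowest passing members of each list described (or, with none passing, the 2 members with the largest absolute mean), and 15 genes chosen in advance. Not every list member under this rule is given in the text. Other genes named in the closing observations were chosen after their values were seen. Alternatives were centring and scaling of the arrays, robust and unmoderated variances, array weights, genes with a value on at least 2 arrays (with camera run on the moderated statistics), a stricter threshold, a test against a 1.5-fold change, leaving out each array in turn, and, for the lists, an estimated correlation, ranks and the rotation test fry. The inclusion of unnamed spots and the reading as natural logs were added after seeing the data. Figures were drawn with matplotlib 3.10.9.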

Results

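The data comprised 3 arrays, each comparing a yeast culture exposed to 5 mM 2-aminobenzimidazole for 2 h with an untreated culture. 2-Aminobenzimidazole is the unsubstituted parent amine of the benzimidazole carbamate fungicides, a class of which some members bind tubulin. The single comparison of the series asked which transcripts differed between exposed and unexposed cells. Every array carried the treated RNA in Cy5, so a dye effect on a gene cannot be told apart from the treatment. Values are log2 ratios of treated over control, a direction that is likely from the channel labels and customary but not stated in the table. Of the 5203 named genes, 3062 had a value on array 1, 5044 on array 2 and 5158 on array 3, and 3039 had a value on all 3.

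After exposure, transcripts of the general stress response, of iron uptake and of arginine and methionine synthesis were higher, and transcripts of cytosolic ribosomal proteins, ribosome assembly and purine synthesis were lower (camera). None of these list calls held in camera with an inter-gene correlation estimated from the arrays (adjusted p = 0.548 to 0.636 with an estimated correlation). That setting leaves 2 degrees of freedom and passed 0 of the 45 tested lists, so the loss is not particular to these lists. The array 2 medians of the arginine and methionine lists were 0.02 and 0.21. Of the 3039 genes tested, 254 (8.36%) were higher and 293 (9.64%) were lower at an adjusted p below 0.05 (limma, Benjamini-Hochberg). The mean change was at least 2-fold for 248 of the higher and 278 of the lower genes. At an unadjusted p below 0.05, 495 genes were higher and 601 lower. The number of calls depended on which arrays were kept: without array 1 or without array 3, 0 genes passed in limma (635 and 715 at an unadjusted p below 0.05). In these 2 fits the means of some genes moved little, as for GAR1 (-2.36 with all arrays, -2.33 and -2.38) and BDH2 (3.05, 2.90 and 3.09), and those of others moved more, as for SNZ1 (4.49, 3.28 and 4.01) and ARG1 (3.92, 2.98 and 3.02). Without array 2, 373 genes were higher and 366 lower, 486 of these 739 being among the 547 genes called from all arrays. Independently of the test, 115 genes were at least 2-fold higher and 114 at least 2-fold lower on each of the 3 arrays.

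The arrays did not repeat each other equally. Across the 3039 genes, which are not independent replicates, the log2 ratios of arrays 1 and 3 correlated with a Pearson r of 0.748 and a Spearman rho of 0.683. The correlation of arrays 1 and 2 was 0.52 (rho 0.529) and that of arrays 2 and 3 was 0.468 (rho 0.48). The sign was shared by all 3 arrays for 1712 genes (56.3%, against 25% for independent signs). Of the 547 called genes 546 shared it, which a call from the same 3 values nearly ensures.

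**Figure D1:**
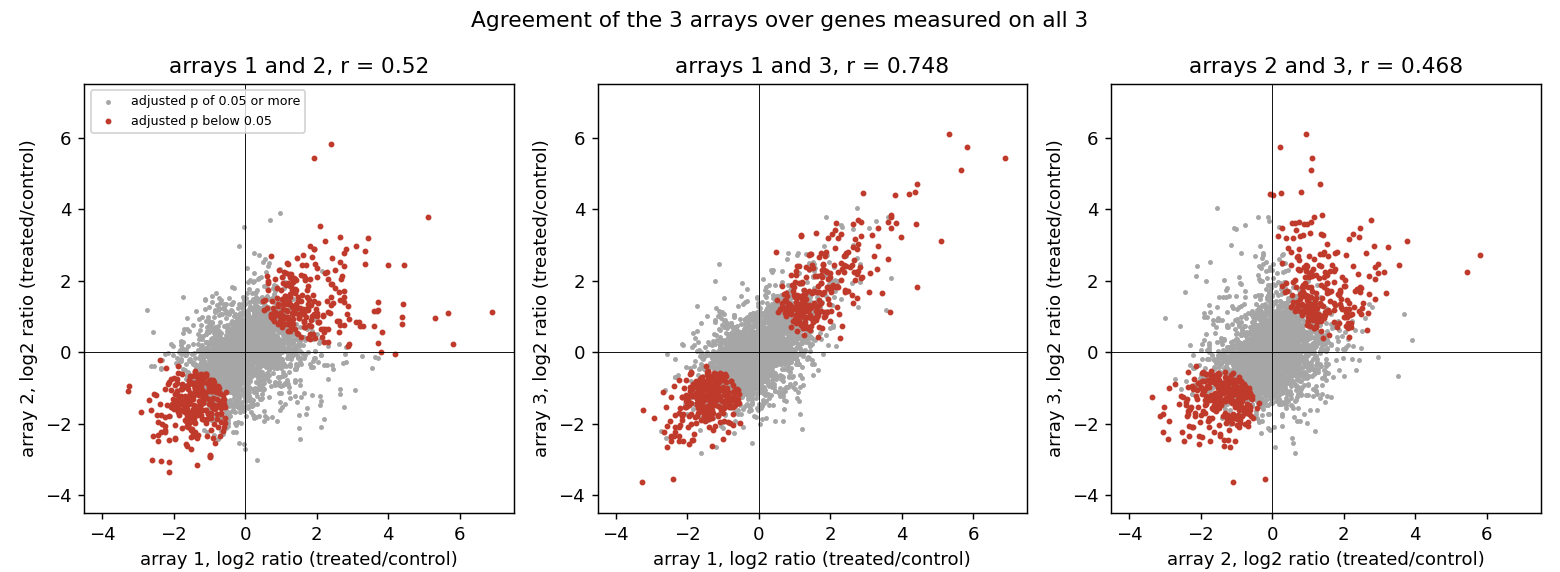
Log2 ratios (treated over control) of the 3039 genes with a value on every array, plotted for each pair of arrays; each point is a gene, and red points passed an adjusted p of 0.05. Arrays 1 and 3 lie closest to a common line (r = 0.748), and several of the highest genes of arrays 1 and 3 are near 0 on array 2.

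The 15 highest genes differed in how alike their 3 arrays were. HSP12 (YFL014W), a membrane-protecting heat shock protein, rose to 3.99 ± 1.02 (log2, SD, n = 3; 15.9-fold; adjusted p = 0.00733, limma). TMT1 (YER175C), a trans-aconitate methyltransferase, rose to 3.21 ± 0.78, PHM7 (YOL084W) to 3.09 ± 0.55, FMP16 (YDR070C) to 3.08 ± 0.55 and BDH2 (YAL061W), a putative butanediol dehydrogenase, to 3.05 ± 0.26, each with at least 2.43 on every array. The highest mean belonged to SNZ1 (YMR096W), a vitamin B6 synthesis gene, at 4.49 ± 3.00 (adjusted p = 0.0234), with 6.89 on array 1, 5.44 on array 3 and 1.12 on array 2. Its divergently transcribed neighbour SNO1 (YMR095C) stood at 3.95 ± 2.49. A lowest value on array 2 was also seen for RTC2 (YBR147W) at 4.12 ± 2.77, for ARG1 (YOL058W), argininosuccinate synthetase, at 3.92 ± 3.20, and for STR3 (YGL184C), a cystathionine lyase of the methionine pathway, at 3.49 ± 1.86. ARO5 (YGL117W) at 3.22 ± 2.10, YHI9 (YHR029C) at 2.99 ± 1.78 and MET17 (YLR303W), which fixes sulfide into homocysteine, at 2.98 ± 1.37 were likewise lowest on array 2. FIT2 (YOR382W), a cell wall protein of iron uptake, at 3.65 ± 1.88, and HSP26 (YBR072W), a small heat shock chaperone, at 3.21 ± 1.94, were instead highest on array 2, with 5.82 and 5.44.

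The 15 lowest genes were closer between arrays. YHB1 (YGR234W), the flavohaemoglobin that detoxifies nitric oxide, had the lowest mean, -2.66 ± 1.38 (adjusted p = 0.0177, limma). URA7 (YBL039C), CTP synthase, fell to -2.54 ± 0.44 and ELO3 (YLR372W), a fatty acid elongase, to -2.39 ± 0.76. Of the small nucleolar ribonucleoprotein genes, GAR1 (YHR089C) fell to -2.36 ± 0.07, NOP1 (YDL014W) to -2.31 ± 0.68, NOP58 (YOR310C) to -2.21 ± 0.15 and NOP56 (YLR197W) to -2.17 ± 0.51. RPA49 (YNL248C), a subunit of RNA polymerase I, fell to -2.35 ± 0.20, and the RNA helicase genes HAS1 (YMR290C) and PRP43 (YGL120C) fell to -2.26 ± 0.27 and -2.19 ± 0.33. The translation factor genes TEF4 (YKL081W) and RPG1 (YBR079C) fell to -2.32 ± 0.26 and -2.18 ± 0.08. AAH1 (YNL141W), adenine deaminase, stood at -2.23 ± 0.42, SRL1 (YOR247W), a cell wall mannoprotein, at -2.25 ± 1.05, and MF(ALPHA)2 (YGL089C), an alpha-factor pheromone gene, at -2.14 ± 0.67.

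**Figure D2:**
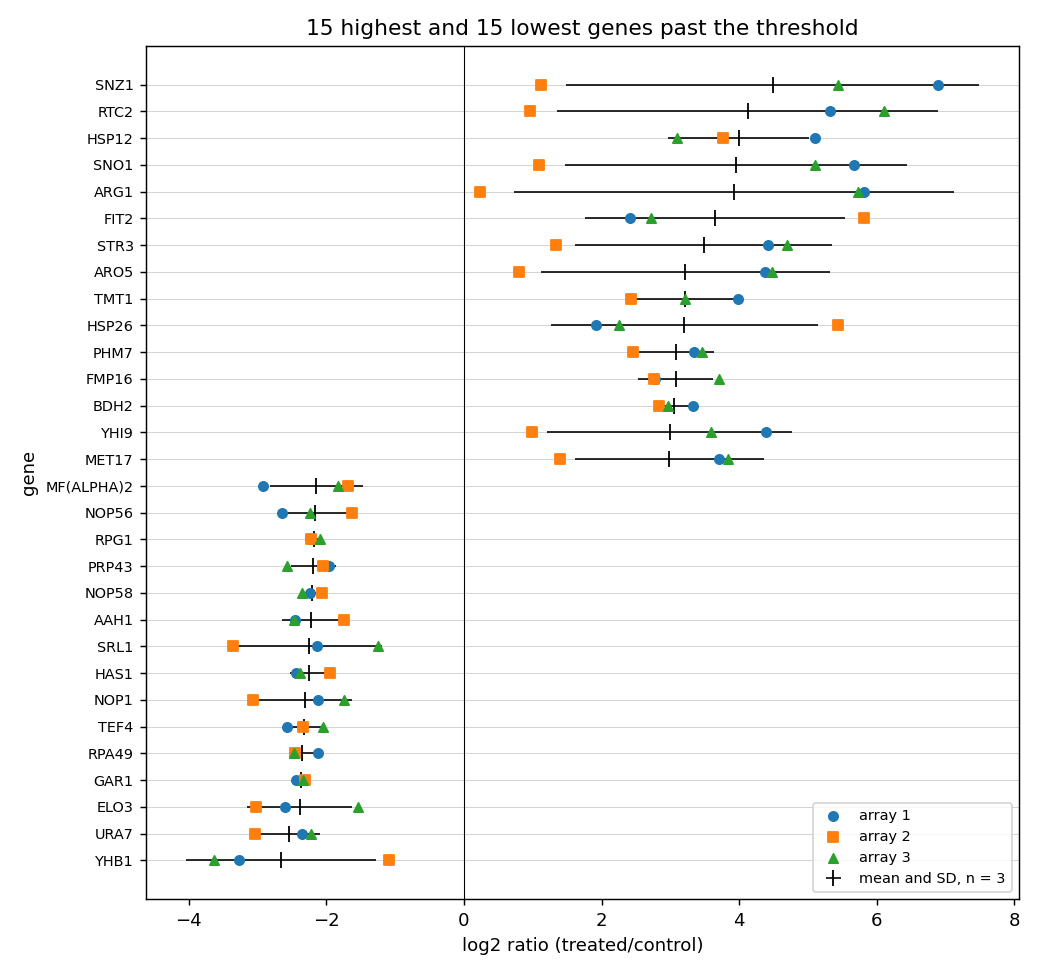
Log2 ratios (treated over control) of the 15 highest and 15 lowest genes past the threshold; coloured symbols are the 3 arrays and black marks the mean with its SD (n = 3). Array 2 lies far below the others for SNZ1, RTC2, SNO1 and ARG1 and above them for FIT2 and HSP26, while GAR1, RPG1 and NOP58 coincide on all arrays.

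Cytosolic ribosomal protein and ribosome biogenesis genes were lower on every array. The 115 tested cytosolic ribosomal protein genes had a median of -0.97 (1.95-fold lower; adjusted p = 2.79e-15, camera; adjusted p = 0.636 with an estimated correlation), with 37 genes lower, 0 higher and 78 not past the threshold (55 lower when adjusted over the list alone). The array medians were -0.52, -1.51 and -0.82 for arrays 1, 2 and 3. Without array 2 the median was -0.64 (adjusted p = 2.13e-07, camera). RPS10A reached -2.11 ± 1.00 and RPS20 -1.93 ± 0.96. Many of these genes have near-identical copies, which a hybridisation array cannot separate with certainty. Of 36 ribosome biogenesis genes, 26 were lower and 0 higher (30 lower adjusted over the list alone), with a median of -1.34 and array medians of -1.33, -1.41 and -1.40 (adjusted p = 3.65e-14, camera; adjusted p = 0.548 with an estimated correlation). Of 10 subunits of RNA polymerases I and III, 6 were lower, among them RPA49 and RPA135 (-1.56 ± 0.70), and 7 were lower adjusted over the list alone (adjusted p = 0.00895, camera; adjusted p = 0.629 with an estimated correlation). Of 29 mitochondrial ribosomal protein genes, 0 passed under either adjustment, and MRPL6 stood at -1.16 ± 0.75 (list adjusted p = 0.597, camera, 0.0384 without array 2, 0.97 without array 1 and 0.694 without array 3; adjusted p = 0.944 with an estimated correlation). The array medians of that list were -0.25, 0.41 and -0.52.

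General stress genes were higher. In the general stress list, targets of the factors Msn2 and Msn4, 16 of 25 genes were higher and 0 lower (19 higher adjusted over the list alone), with a median of 1.47 (2.77-fold) and array medians of 1.59, 1.75 and 1.15 (adjusted p = 1.1e-10, camera; adjusted p = 0.548 with an estimated correlation). SOL4, a phosphogluconolactonase-like gene, stood at 2.90 ± 1.37 beside HSP12. The osmotic stress and glycerol list had a median of 1.04, with 3 of 6 genes higher (4 adjusted over the list alone; camera adjusted p = 0.00323), including GCY1 at 1.39 ± 0.76 (adjusted p = 0.0548 without array 2, limma). Its highest passing gene was HXT5, which is also in the hexose transporter list, so these list calls share a gene. Of 11 hexose transporter genes, HXT5, a transporter of slow-growing cells, at 2.44 ± 0.29, and HXT6, 2.83-fold up, were higher (2 also adjusted over the list alone; camera adjusted p = 0.00297), and HXT6 has a near-identical copy. The median of that list was 0.55, and 0.904 without array 2. Of 10 autophagy and vacuolar protease genes, 4 were higher (5 adjusted over the list alone), with a median of 0.90 (adjusted p = 0.00354, camera), led by APE1 at 1.72 ± 0.25 and ATG8 at 1.32 ± 0.69 (adjusted p = 0.0567 without array 2, limma). Of 11 genes of fatty acid oxidation and peroxisomes, 4 were higher, CRC1 at 1.73 ± 0.21 and POT1 at 1.52 ± 0.63 leading (4 adjusted over the list alone; camera adjusted p = 0.0118, and 0.0505 without array 3). Of 17 genes of the TCA and glyoxylate cycles, 4 were higher (4 adjusted over the list alone), PYC1 at 1.42 ± 0.74 and CIT2 at 1.35 ± 0.72 leading (camera adjusted p = 0.0447, 0.233 without array 2 and 0.0575 without array 3). The median of that list was 0.28, and 0.485 without array 1, and the call of CIT2 was lost without array 2 (adjusted p = 0.0568, limma). For the osmotic, hexose transporter, autophagy, fatty acid oxidation and TCA lists alike, camera gave adjusted p = 0.629 with an estimated correlation.

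The heat shock chaperone list did not pass (adjusted p = 0.072, camera). Of its 21 genes, 4 were higher, including HSP26 and HSP30 (1.68 ± 0.99), and SSB2 was lower at -1.22 ± 0.62, a call lost without array 2 with an adjusted p of 0.0694 in limma (5 higher and 1 lower adjusted over the list alone). Its array medians were 0.06, 1.18 and -0.15, and the call appeared without array 1 (adjusted p = 0.00716, camera), without array 3 (0.0121) or with the 24 genes that had a value on at least 2 arrays (0.036). Without array 2 the list had an adjusted p of 0.958 and a median of -0.063, and with all arrays it had adjusted p = 0.804 with an estimated correlation. The proteasome list also did not pass (adjusted p = 0.622, camera), and 0 of 36 genes passed, also when adjusted over the list alone. RPN11 stood at 0.95 ± 0.32 and RPN9 at -0.75 ± 0.85. The array medians were 0.035, 0.66 and -0.58. The list passed without array 3 (adjusted p = 0.0121, camera) but not without array 1 (0.602) or array 2 (0.153). With all arrays it had adjusted p = 0.95 with an estimated correlation. RPN4, the transcription factor of proteasome genes, stood at 0.33 ± 0.31 (adjusted p = 0.426, limma).

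Amino acid synthesis genes were higher on arrays 1 and 3. The arginine and ornithine list had a median of 2.10 (4.28-fold), with 5 of 7 genes higher (7 adjusted over the list alone; camera adjusted p = 0.00168), but its array medians were 2.87, 0.02 and 3.41. ARG4, argininosuccinate lyase, stood at 2.85 ± 2.52 and lost its call with centred arrays, scaled arrays or a robust variance (adjusted p = 0.052, 0.0544 and 0.0585, limma). Of 18 sulfate assimilation and methionine genes, 6 were higher and 0 lower (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00228), with array medians of 2.12, 0.21 and 1.73. The median of that list was 1.31, against 0.833 without array 1, 1.98 without array 2 and 0.642 with its 28 genes that had a value on at least 2 arrays. Of 8 lysine synthesis genes, only LYS1 at 2.48 ± 1.92 passed over all genes, and 4 did adjusted over the list alone; camera gave an adjusted p of 0.0385 with all arrays, 0.146 without array 1 and 0.154 without array 3. Its median was 1.19, and 1.79 without array 2. With an estimated correlation the arginine and methionine lists had adjusted p = 0.629 and the lysine list adjusted p = 0.692. The lists for histidine (median 1.28), for leucine, isoleucine and valine (0.57) and for aromatic amino acids (0.79) did not pass with all arrays, with adjusted p of 0.072, 0.115 and 0.106 (camera). Their medians on array 2 were -1.21, -1.29 and -0.75, and on array 1 they were 1.88, 1.52 and 1.44. Without array 2 the 3 lists passed, with adjusted p of 9.23e-05, 8.97e-05 and 4.08e-05 (camera), but not without array 1 (0.284, 0.407 and 0.428) or without array 3 (0.247, 0.52 and 0.597), where the medians were 0.608, 0.007 and 0.123. With all arrays they had adjusted p = 0.69, 0.782 and 0.804 with an estimated correlation. HIS2 (1.28 ± 0.80) and LEU2 (2.05 ± 0.63) passed on their own (HIS2 with an adjusted p of 0.0502 in limma when genes on at least 2 arrays were tested), and 0 of 13 aromatic genes did, with ARO3 at 1.70 ± 2.21. These 3 lists had 2, 1 and 0 genes higher adjusted over the list alone. The nitrogen catabolite list had a median of 1.02, with 5 of 12 genes higher (7 adjusted over the list alone; camera adjusted p = 0.00209), including the permease genes GAP1 at 1.77 ± 0.60 and MEP2 at 1.74 ± 1.33 (list adjusted p = 0.629 with an estimated correlation).

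Purine synthesis genes were lower. Of 19 purine synthesis genes, 9 were lower and 0 higher (11 lower adjusted over the list alone), with a median of -1.03 (2.05-fold lower) and array medians of -1.06, -1.60 and -0.78 (adjusted p = 0.000263, camera; adjusted p = 0.629 with an estimated correlation). SHM2, serine hydroxymethyltransferase, stood at -2.09 ± 0.94 and GUA1, GMP synthase, at -2.03 ± 0.29. In the pyrimidine list, which did not pass as a whole (adjusted p = 0.17, camera), URA7 and URA5 (-1.61 ± 0.12) were among 3 lower genes, and URA10, a minor copy of the URA5 enzyme, was higher at 2.15 ± 0.54 (the same counts adjusted over the list alone).

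Iron uptake genes were higher. Of 18 genes of the iron regulon, 5 were higher and FRE1 (-1.17 ± 0.45) was lower (9 higher and 1 lower adjusted over the list alone), with a median of 0.96 (adjusted p = 0.000368, camera; adjusted p = 0.629 with an estimated correlation) and array medians of 0.57, 1.55 and 0.55. Without array 2 the median was 0.616 (adjusted p = 0.0103, camera). Beside FIT2, the siderophore transporter gene ENB1 stood at 1.88 ± 0.79. The zinc and phosphate list did not pass (adjusted p = 0.622, camera), with PHM7 higher and PHO11, an acid phosphatase with near-identical copies, lower at -2.05 ± 1.70 (1 higher and 0 lower adjusted over the list alone). The call of PHO11 was lost with scaled arrays or a robust variance (adjusted p = 0.052 and 0.056, limma). In the copper list CUP1-1, the metallothionein gene, passed at 1.37 ± 0.95, though not without array 2 or with genes on at least 2 arrays, where limma gave adjusted p of 0.0574 and 0.0517 (1 adjusted over the list alone; camera adjusted p = 0.27).

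Drug efflux genes had a median of 0.49, with array medians of 0.27, 0.08 and 1.02 and a median of 0.311 without array 3. Of 17 genes 2 passed, the polyamine transporter genes TPO2 at 1.71 ± 0.47 and TPO3 at 1.58 ± 1.16 (4 adjusted over the list alone; camera adjusted p = 0.0385, and 0.169 without array 3; adjusted p = 0.657 with an estimated correlation). The call of TPO3 was lost with array weights (adjusted p = 0.0502, limma). PDR5, the main multidrug efflux pump, stood at 0.88 ± 1.81 (adjusted p = 0.338, limma), with -0.19, 2.96 and -0.15 on arrays 1, 2 and 3, and its mean without array 2 was -0.17. FLR1, a transporter of benzimidazole fungicides, stood at 0.41 ± 0.47 (adjusted p = 0.358, limma) and YAP1, the factor that controls it, at 0.53 ± 0.34 (adjusted p = 0.215, limma). The list of Yap1 and oxidative stress targets did not pass (adjusted p = 0.288, camera). Of its 21 genes GTT1, a glutathione transferase, at 1.69 ± 0.40 and TRX2, a thioredoxin, at 1.01 ± 0.38 were higher (1 adjusted over the list alone). The call of TRX2 (adjusted p = 0.0482, limma) was lost with scaled arrays (0.0556), without array 2 (0.0873) and with genes on at least 2 arrays (0.0566). With 27 genes that had a value on at least 2 arrays the list passed (adjusted p = 0.036, camera; with all arrays, adjusted p = 0.804 with an estimated correlation). The putative aryl-alcohol dehydrogenases, which are close copies of each other, had 0 of 5 genes past either adjustment and a list adjusted p of 0.0923 (camera; 0.141 without array 1, 0.351 without array 2, 0.0284 without array 3 and 0.0168 with 7 genes on at least 2 arrays; adjusted p = 0.658 with an estimated correlation), with AAD4 at 0.72 ± 0.42.

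Of the genes of the tubulin list, TUB2, the beta-tubulin gene, was lower at -1.58 ± 0.43 (adjusted p = 0.0174, limma), with -1.91, -1.10 and -1.74 on the 3 arrays. Only 3 of the list's genes had values on all arrays, and the list did not pass (adjusted p = 0.115, camera; 1 gene lower adjusted over the list alone), while the rotation test fry called it (adjusted p = 0.0298). With 12 genes that had a value on at least 2 arrays, its median was -0.133 instead of -0.684 (adjusted p = 0.35, camera). TUB1, TUB3, SNQ2, ADE17 and ERG11 were not analysed here. Spindle motor genes (5 tested, adjusted p = 0.775, camera) and spindle checkpoint genes (3 tested, adjusted p = 0.804, camera) had 0 genes past the threshold under either adjustment. Of the motor genes, KIP3 stood at -0.84 ± 0.67 and STU2 at -0.71 ± 0.68. Of the checkpoint genes, MAD1 stood at -0.73 ± 0.38 and MAD2 at 0.57 ± 0.21.

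Cell cycle lists did not pass with the genes measured on all 3 arrays. G1 and S-phase genes had a median of -0.40 (0 of 7 passed; adjusted p = 0.279), G2 and mitosis genes -0.82 (0 of 5 passed, 2 lower adjusted over the list alone; adjusted p = 0.138), early G1 genes 0.28 (1 of 12 passed, MCM3 at -1.05 ± 0.19, and 0 adjusted over the list alone; adjusted p = 0.427) and core histones -0.41 (0 of 8 passed under either adjustment; adjusted p = 0.185), all by camera. Only 7 of 15 measured G1 and S-phase genes and 5 of 15 measured G2 and mitosis genes had a value on all 3 arrays, and with genes on at least 2 arrays both lists were lower. The 15 such G1 and S-phase genes had a median of -0.713 (adjusted p = 0.00753, camera) and the 15 G2 and mitosis genes -0.823 (adjusted p = 0.00164). The genes added in this way each lack a value on 1 array. Among genes on all 3 arrays, neither list passed without array 1 (adjusted p = 0.284 and 0.245, camera), without array 2 or without array 3. In the fit of all 3 arrays the G1 list had adjusted p = 0.655 with an estimated correlation and the G2 list adjusted p = 0.629 with an estimated correlation, and fry called the G1 and S-phase list there (adjusted p = 0.0298). The cyclin genes CLN2 and CLB2 had no value on array 1 and stood at -1.72 and -1.96 on array 2 and at -1.27 and -1.16 on array 3. Their adjusted p were 0.0397 and 0.0405 when genes on at least 2 arrays were tested (limma). That fit borrows its spread from genes with 3 arrays too. Fitted from arrays 2 and 3 alone, the genes with values on all arrays gave 0 calls (lowest adjusted p = 0.168, limma). MET3, also without a value on array 1, stood at 0.07 and -0.41. In the DNA damage list (8 tested, adjusted p = 0.993, camera), whose median of -0.26 and mean of 0.06 differ in sign, RNR1 was lower at -1.58 ± 0.36 and UBI4 (1.70 ± 0.84) and DDR48 (1.41 ± 0.88), which are also general stress genes, were higher (3 higher and 1 lower adjusted over the list alone). The call of DDR48 was lost without array 2 (adjusted p = 0.0726, limma). RNR3, a damage-induced ribonucleotide reductase gene, stood at -0.79 ± 0.82 (adjusted p = 0.156, limma).

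Among the remaining lists, the mating type alpha genes were lower, with a median of -1.08 and 2 of 4 genes past the threshold (3 adjusted over the list alone; camera adjusted p = 0.0245; adjusted p = 0.629 with an estimated correlation), including SAG1 at -1.24 ± 0.45. All 6 mating type a genes lacked a value on at least 1 array, so 0 were tested, and the pheromone response list did not pass (0 of 8 genes; adjusted p = 0.725). Cell wall genes went both ways, with 5 of 19 higher, including SED1 at 1.63 ± 0.76, and 3 lower, including GAS1 at -1.56 ± 0.43 (7 higher and 3 lower adjusted over the list alone; adjusted p = 0.279). In fatty acid and phospholipid synthesis 4 of 14 genes were lower, ELO3 and ELO2 (-1.52 ± 0.62) leading (1 higher and 4 lower adjusted over the list alone; adjusted p = 0.0863, 0.172 without array 1, 0.0458 without array 2 and 0.123 without array 3). In ergosterol synthesis ERG7 alone of 21 genes was lower, at -1.47 ± 0.46 (1 adjusted over the list alone; adjusted p = 0.072, 0.258 without array 1, 0.014 without array 2, 0.169 without array 3 and 0.036 with 23 genes on at least 2 arrays). In the unfolded protein list 3 of 15 genes were lower, including SEC61 at -1.82 ± 0.32 (3 adjusted over the list alone; adjusted p = 0.355). Respiratory chain genes had 1 higher, COX5B at 1.25 ± 0.35, and 2 lower, CYT1 at -1.45 ± 0.59 and COX6 at -1.37 ± 0.33 (the same counts adjusted over the list alone; adjusted p = 0.918). Glycolysis and fermentation had ADH5 higher at 1.99 ± 1.46 and PDC5 lower at -1.35 ± 0.66 (0 adjusted over the list alone; adjusted p = 0.673). The thiamine and vitamin B6 list had 3 of 9 genes higher, SNZ1 and SNO1 leading (3 adjusted over the list alone; adjusted p = 0.147, 0.0466 by fry and 0.036 with 18 genes on at least 2 arrays), and the sporulation list had SPS100 higher at 1.58 ± 0.78 (1 adjusted over the list alone; adjusted p = 0.0531, 0.0252 without array 1, 0.0695 without array 2, 0.129 without array 3 and 0.00753 with 10 genes on at least 2 arrays). With all arrays, the fatty acid and phospholipid, thiamine and sporulation lists had adjusted p = 0.629 with an estimated correlation, and the ergosterol list adjusted p = 0.657. List p-values in this paragraph are from camera unless fry is named.

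**Figure D3:**
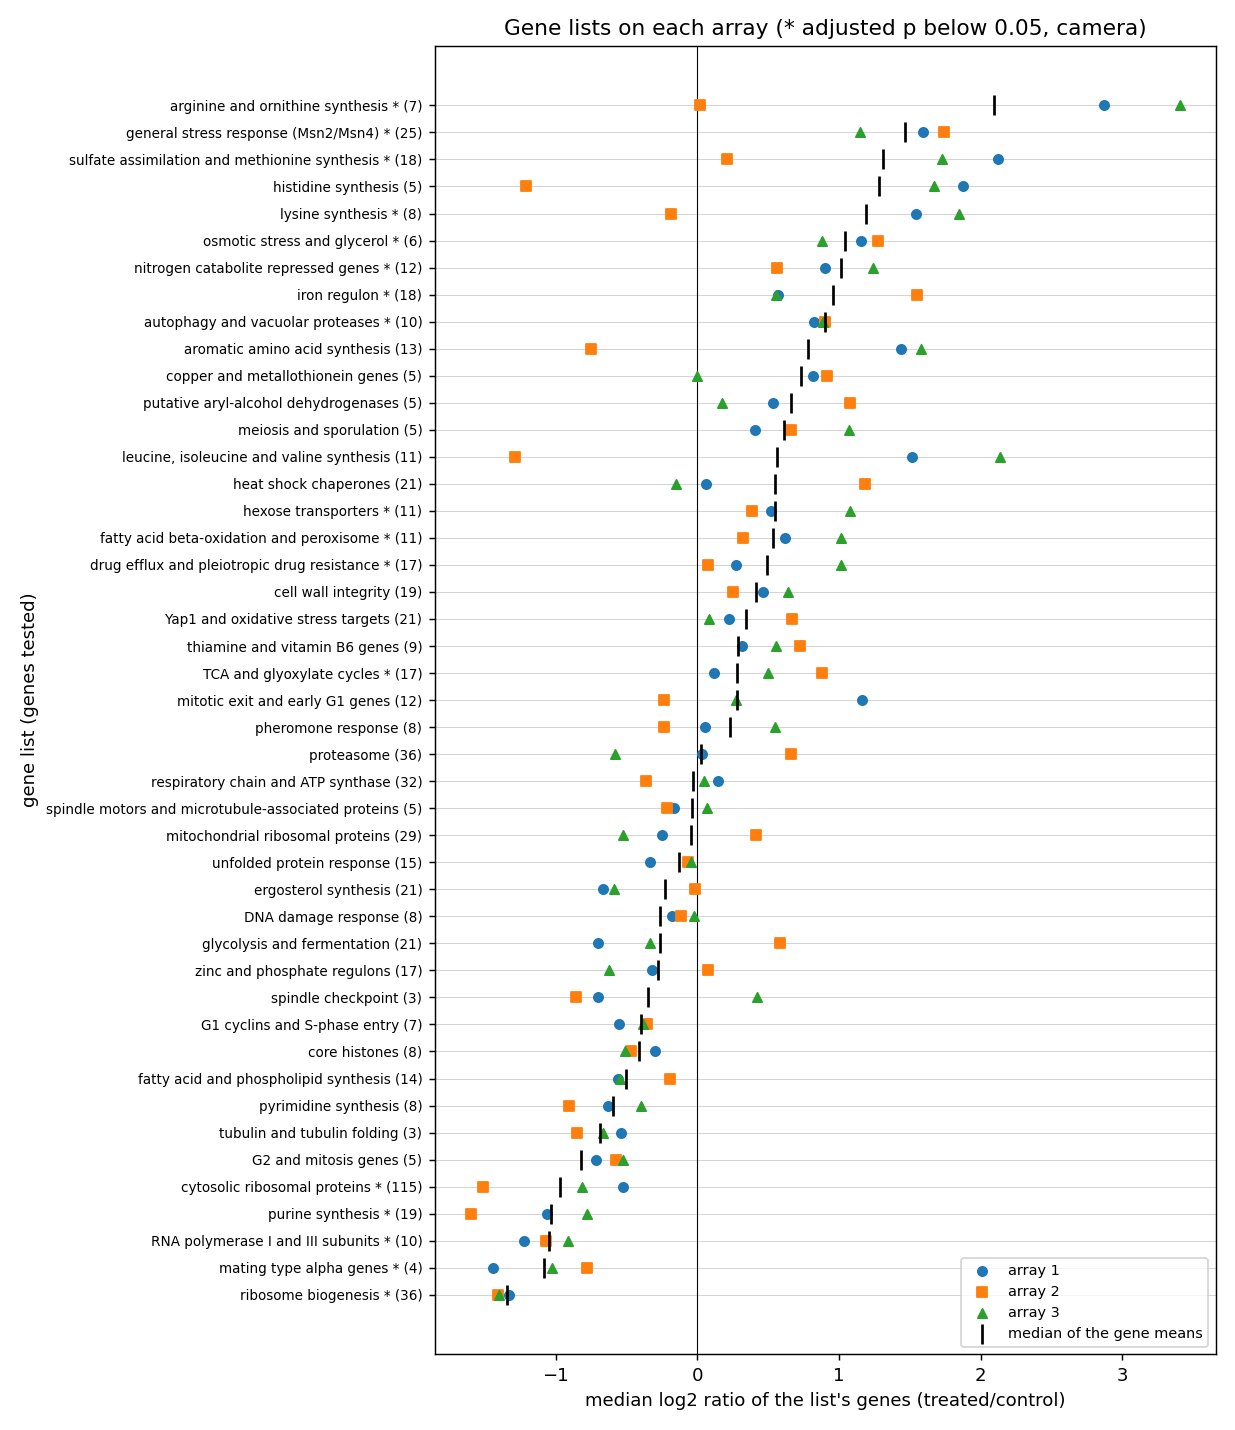
Median log2 ratio (treated over control) of each tested gene list on each array (coloured symbols) and the median of the genes' means (black mark); the number of genes tested is in brackets and an asterisk marks an adjusted p below 0.05 in camera. Ribosome biogenesis and autophagy genes coincide on the 3 arrays, while on array 2 arginine genes stand at 0.02 against 2.87 and 3.41 on the others.

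In total 17 of the 45 tested lists passed, 12 of them higher and 5 lower, and 13 of the 17 passed in each fit with 1 array left out. The camera setting matters for these calls. With a correlation estimated from the arrays, which leaves 2 degrees of freedom, 0 of the 45 lists passed in camera. The 17 among them had adjusted p = 0.548 to 0.692 with an estimated correlation. Calls were lost also where the estimate was near the preset 0.01, as for ribosome biogenesis (0.0144) and general stress (0.0202). The estimate was 0.954 for arginine, 0.92 for lysine and 0.682 for cytosolic ribosomal proteins. The loss can therefore not be put down to correlated genes alone, and the effect of the 2 degrees of freedom was not tested apart. The rotation test fry, which asks whether a list's genes move one way rather than comparing them with other genes, called 7 lists. Of these, the general stress, ribosome biogenesis, osmotic and autophagy lists were among the 17, and the tubulin, G1 and S-phase, and thiamine and vitamin B6 lists were not. With genes that had a value on at least 2 arrays, 25 of 46 lists passed in camera, the 17 and 8 more, all at the preset correlation.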

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

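Gene counts stayed within 1.5 times of the 254 higher and 293 lower genes, or of the 248 and 278 changed at least 2-fold, without array 2 and with centring, scaling, robust variances, array weights, genes on at least 2 arrays, unnamed spots and natural logs (the last 2 settings chosen after seeing the data). With no moderation of the variance, all 4 counts were 0 (limma's moderated test at an unadjusted p below 0.05 gave 1096 genes). At an adjusted p of 0.01, 23 genes were higher and 13 lower, with the same counts at least 2-fold. Tested against a 1.5-fold change, 29 genes were higher and 16 lower by at least 2-fold. Leaving out 1 array gave between 0 and 373 higher and between 0 and 366 lower genes, and between 0 and 363 and between 0 and 357 at least 2-fold; the zeros are without array 1 and without array 3. Each such fit has 2 arrays and borrows its spread from all genes. The fit without array 2 also has 2 arrays and gave 739 calls, so the number of arrays alone does not account for the zeros. Both fits with 0 calls kept array 2, and their prior degrees of freedom were 4.07 and 3.97, against 7.65 without array 2. The cause beyond this was not tested. Of 45 lists, 17 passed; an estimated inter-gene correlation gave 0, fry 7, leaving out 1 array 16 to 22, and genes on at least 2 arrays 25, which adds the G1, G2, Yap1, aryl-alcohol, heat shock, ergosterol, thiamine and sporulation lists. Without the called genes, the correlation of arrays 1 and 2 was 0.199, of arrays 1 and 3 0.538, and of arrays 2 and 3 0.132. A lower correlation is built in here, because the called genes were selected for agreement on the same arrays. With genes on at least 2 arrays, 2 lists that did not pass in camera changed the sign of their median, the respiratory chain to 0.031 and the DNA damage list to 0.227. With 1 array left out, the median of early G1 genes lay between -0.07 and 0.448, of heat shock chaperones between -0.063 and 0.751, of the proteasome between -0.267 and 0.334, of mitochondrial ribosomal proteins between -0.287 and 0.153 (0.058 without array 1), of glycolysis between -0.448 and 0.062, of the pheromone response between -0.086 and 0.267, and the mean of PDR5 between -0.166 and 1.407. The cause of these sign changes was not tested. No paired analysis was possible because the series has a single group, in which each array is already a ratio of treated over control. Signal over background is unknown here, and the 2141 genes without a value on array 1 lie outside the test.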

Other observations

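Tests of spot position, Gcn4 targets, another treatment, gene length and dye were written down before their results were seen, and those on missing values of array 1 after. All genes named in this section outside the report were chosen after their values were seen.

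Beyond the genes tested on all arrays, 1982 genes had values on arrays 2 and 3 only. Of these, 45 were at least 2-fold higher and 59 at least 2-fold lower on both arrays. The ribosome assembly genes NOP7 (-2.43 and -2.94 on arrays 2 and 3), RIX1 (-1.87 and -2.20) and NOP13 (-1.80 and -1.85) were low, as was the G1 cyclin gene CLN1 (-1.40 and -1.37). ZWF1, the first enzyme of the pentose phosphate pathway, stood at 1.83 and 2.37, NQM1, a transaldolase-like gene, at 3.78 and 1.99, and the biotin genes BIO5 and BIO2 at 2.47 and 2.09 and at -1.52 and -2.19. HMX1, haem oxygenase, stood at 2.75 and 1.45, and FIT1 of the iron regulon at 2.02 and 1.44. Of the 179 unnamed spots with a value on every array, 8 were higher and 19 lower when tested together with the named genes (limma, adjusted p below 0.05).

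Open reading frames of the Ty1 and Ty2 retrotransposons went opposite ways between arrays. Of 18 with values on all 3, 16 were above 0 on array 2 and below 0 on arrays 1 and 3, with medians of -0.76, 1.01 and -1.15. These elements are near-identical repeats, so the 18 spots are far from independent. The secreted acid phosphatase genes PHO5 (-2.74, 1.19 and -2.21 on arrays 1, 2 and 3) and PHO3 (-2.59, 0.57 and -2.39) were likewise above 0 on array 2 only, and CHA1, the serine and threonine deaminase gene, stood at -0.04, 3.51 and -0.67. In the proteasome list 31 of 36 genes were highest on array 2, as were 19 of 21 heat shock chaperone genes and 15 of 18 genes of the iron regulon.

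The pattern that most invites a second look is that 62 genes of the 6 amino acid lists had medians of 1.89 on array 1, 1.99 on array 3 and -0.31 on array 2, with 57 of the 62 higher on both arrays 1 and 3 than on array 2. Spot position was argued against: reading the spot numbers as block, row and column, and centring each array by these, left the median difference at 2.36 (95% bootstrap interval 2.02 to 2.71) against 2.31 before. The bootstrap resampled the 62 genes as if independent, so the interval does not measure the spread between arrays. Noise in the spots of these genes was also argued against, since 19 other targets of Gcn4, the activator of amino acid synthesis genes, had a median difference of 2.06, at percentile 100 of 10000 random lists (central 95%, -0.38 to 0.458). What stays open is whether array 2 holds RNA of another treatment or a culture in another state. Outside the stress and ribosome lists, 82.2% of the 670 genes called from arrays 1 and 3 had their sign on array 2. That percentage cannot decide, since another stress could give the same signs. A dye effect common to the arrays, which all carried the treated RNA in Cy5, could also give them for an unrelated or untreated pair. No biological explanation was tested. Levels of Gcn4 target transcripts in each culture, from the separate channels or by RT-PCR, would show whether the treated or the control culture differs, and were not analysed here.

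Lower ribosomal protein transcripts could reflect the short length of these genes or a dye effect. Gene length as listed in the RefSeq table is argued against: 115 other genes matched on it (median 798 bases against 799) had a median of 0.17 (0.0505 to 0.288, 95% bootstrap). This is 1.14 above the -0.97 of the ribosomal protein genes (-1.03 to -0.88). The bootstrap resampled genes as if independent, so these intervals do not measure the spread between arrays. Whether the listed length counts introns was not examined, so an effect of transcript length is not settled. Dye bias cannot be told apart from the treatment, for these or any other genes, because 0 arrays carried the treated RNA in Cy3.

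Array 1 lacked a value for 2951 of 6272 spots. Weak spots are a candidate source: of the spots without a value on array 1, 22.6% also lacked one on array 2 or 3, against 1.23% of the others, a ratio of 18.3. Loss of nearly all spots of a whole block is argued against, since the share without a value lay between 31.6% and 57.7% in all 32 blocks. The share still differed between blocks, and the test could not exclude a smaller or partly damaged region. If weak spots are the source, the genes tested on all 3 arrays may be mostly the better expressed ones.

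Turning the sign of 1 array gives 3 further patterns beside the real one, too few for a share under 0.05. The real pattern gave 547 genes, the highest of the others gave 0, and 1 of 4 patterns reached the real count.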
